A study of Homo sapiens with 9 samples.

How the data were processed

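RNA was measured by RNA-seq in 9 libraries of MDA-MB-231, a human triple-negative breast adenocarcinoma cell line. The libraries form 3 groups of 3, taken from the sample titles. Control cells carried the empty pLKO.1 lentiviral vector, knockdown cells carried the same vector with a short hairpin RNA against ACSL4, and the third group was control cells given PRGL493, an ACSL4 inhibitor. The labels give no dose, exposure time or vehicle for PRGL493. Total RNA was extracted with Trizol and libraries followed Illumina's protocol, per the labels' protocols.

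The deposited table holds 26475 rows of gene symbols and a column of estimated counts per library, not scaled for depth. Of its values 10.5% were not whole numbers, so they were taken for expected counts and rounded to whole numbers before testing. Reads were placed on GRCh38, per the submitters' processing notes. The aligner, the counting tool, the annotation release and whether counting used the strand are not given in the sources used here. Counts of genes that overlap another gene, or that share sequence with a near-identical copy, are therefore uncertain. In 28 rows a spreadsheet had turned the symbol into a date, 4 of these rows shared a name, and together they held between 0.236% and 0.258% of the counts of each library. They stayed in the library totals and in the tests but were not named. No read was counted in 6932 rows. The design had assumed whole counts. The test it names also fits rounded expected counts and was kept.

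Library totals ran from 28673940 to 43027217 counts. Genes were filtered with edgeR's filterByExpr, which left 14135 genes, and scaled with TMM factors. A quasi-likelihood model (edgeR 4.0.16 in R 4.3.3, glmQLFit with robust estimation) was fitted to all 9 libraries with group as its only term, which left 6 residual degrees of freedom. The biological coefficient of variation was 6.38%. The contrasts were knockdown against control, PRGL493 against control, and knockdown against PRGL493. The p-values were adjusted by Benjamini-Hochberg over all genes tested in a contrast, and genes with an adjusted p below 0.05 were called. Levels are TMM-scaled CPM (counts scaled to a common library total) given as mean ± SD over 3 libraries, and log2 fold changes carry the standard error (SE) that the model implies. Every adjusted p of a gene comes from this edgeR test.

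The series describes the 3 libraries of a group as separate batches of cells, so p-values measure the spread between batches of the same engineered cells. They do not cover differences between independently transduced populations, between hairpins or between cell lines.

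Before the data were examined, 41 gene lists, the test, the comparisons, the rule for named genes and all but 2 of the alternatives were fixed. Of the 1135 listed members 1121 matched a row, current symbols being matched to older ones through published synonyms. A list of transcripts encoded in the mitochondrial genome had no matching row, and 40 lists were tested. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. This asks whether a list's members moved further than other genes. The test was repeated with a correlation estimated from the residuals. The fry test, which asks only whether the members move on balance in a single direction, was run as an alternative. With the estimated correlation 6 of the 15 list calls in knockdown against control held, those of immediate early genes, inflammatory genes, G1/S genes, G2/M genes, breast stem-like genes and p53 targets. The camera adjusted p was then 0.013 for immediate early genes and 0.047, just under the threshold, for each of the others. With that correlation camera called 0 of 40 lists in PRGL493 against control and 0 of 40 in knockdown against PRGL493. At an unadjusted p below 0.05 it listed 16 and 8, and fry called 31 and 33. With the estimated correlation and the length and GC trend removed together, a pair of choices made after seeing the data, 5, 5 and 7 lists were called in the 3 comparisons, and breast stem-like genes in knockdown were not (adjusted p = 0.056). In each called list the median, the mean and the test had the same sign. For each list the number of members called is also given with p-values adjusted over the list alone.

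The text names ACSL4 and SNAI1 in every comparison. It also names, for each treatment against control, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among called genes with a mean log2 CPM of at least 2, no overlap between the 3 libraries of either group, and an established symbol. Up to 4 called members of each described list with the smallest adjusted p are named. Across both treatments the rule takes the 6 genes per direction called alike, and the 4 genes called in opposite directions, whose smaller change was largest. The limits on level and symbol were added to this part after the data were seen, and genes under both forms are named. For knockdown against PRGL493 it takes 4 genes per direction. Not every gene that the rule takes is named.

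Both treatments were compared with the same 3 control libraries, so their fold changes share chance values. The overlap and correlation are therefore set beside 100 simulations in which the treated groups were unchanged but shared those controls. Coordinates, transcript lengths and GC content came from GENCODE release 29 on GRCh38, and 97.3% of tested genes had a length and a GC content. Both were those of the longest annotated transcript of a gene, which need not be the one expressed.

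The method was tested on simulated counts drawn from the real means, dispersions and library sizes. Of 50 genes changed at each size, 1.25-fold changes were recovered for 30 genes in knockdown against control (13972 genes tested), 27 in PRGL493 against control (13978 genes) and 34 in knockdown against PRGL493 (13991 genes). For 1.5-fold changes the numbers were 50, 49 and 49. Unchanged genes made up 7 of 186 calls, 11 of 187 and 16 of 198. Of 4 lists shifted by 1.2-fold, 4 were recovered in each comparison with the preset correlation and 2, 4 and 3 with the estimated one. Unchanged lists were called in 1 of 30, 0 of 26 and 0 of 30 cases. Genes were drawn independently of each other in these simulations. They therefore do not show how often lists whose genes vary together are falsely called (estimated correlation 0.65 for cytosolic ribosomal proteins). A simulated trend with transcript length, alike in all 3 knockdown libraries, gave 1249 calls in knockdown against control (13981 genes). After removal of the length and GC trend 0 were left. A GC trend, or a trend held by a single library, was not simulated.

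The alternatives were DESeq2 size factors, upper-quartile factors and library size alone in place of TMM, no filter on low counts and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom in place of edgeR, a fit on the 2 compared groups only, the replicate number as a block, leaving out each library in turn, an adjusted p below 0.01, and a test against a 1.2-fold change (glmTreat). An alternative chosen after seeing the data removed a smooth trend of each library with transcript length and GC content, alone or together with the estimated correlation.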

Results

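RNA abundance was measured in MDA-MB-231 cells, a triple-negative breast cancer line, in 3 groups of 3 libraries. The groups were empty-vector control cells, cells with a short hairpin RNA against ACSL4, and control cells given the ACSL4 inhibitor PRGL493. Totals were 30845845, 31326923 and 33020202 counts in the control libraries. They were 43027217, 37833352 and 38467016 in the knockdown libraries and 41310083, 28673940 and 32115787 in the PRGL493 libraries. The first 3 principal components of log2 CPM carried 40.4%, 24.2% and 8.54% of the variance. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of at least 4.08 for every pair. The value was 34.1 between knockdown replicates 1 and 2, 19.4 between 2 and 3, and 8.83 between 1 and 3. In knockdown replicate 2, genes with short transcripts (up to 2228 bp) lay a median log2 of 0.18 above their mean over all libraries. Genes with long transcripts (over 6041 bp) lay at -0.19. In the other libraries both medians lay between -0.07 and 0.07.

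ACSL4 encodes a long-chain acyl-CoA synthetase that prefers arachidonic acid and other polyunsaturated fatty acids. It lies on the minus strand of chromosome X, from 109624244 to 109733403 on GRCh38, where it overlaps KCNE5 on the same strand. Its level was 342, 339 and 366 CPM in the control libraries, 29.5, 23.7 and 27.6 CPM in the knockdown libraries, and 333, 350 and 360 CPM in the PRGL493 libraries. In knockdown cells ACSL4 was at 7.73% of control (27.0 ± 2.95 against 349 ± 14.8 CPM, SD, n = 3, log2 fold change -3.69, SE 0.07, adjusted p = 6.0e-16). With PRGL493, which acts on the enzyme, ACSL4 RNA differed from control by less than the spread between replicates (348 ± 13.7 CPM, log2 fold change -0.01, SE 0.06, adjusted p = 0.95).

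The series links ACSL4 to histone H3 acetylation and to SNAIL, a repressor of E-cadherin that drives epithelial-mesenchymal transition and is encoded by SNAI1 (chromosome 20, 49982999 to 49988886, plus strand). SNAI1 was low in all cells and fell in both treatments. It was at 11.1, 10.6 and 10.4 CPM in the control libraries, at 1.87, 2.50 and 2.15 CPM in the knockdown libraries and at 2.75, 2.24 and 2.54 CPM in the PRGL493 libraries. Counts behind these levels ran from 326 to 339 per control library, 82 to 95 per knockdown library and 64 to 113 per PRGL493 library. The fall was 4.91-fold in knockdown cells (log2 fold change -2.30, SE 0.12, adjusted p = 4.8e-10) and 4.22-fold with PRGL493 (log2 fold change -2.08, SE 0.12, adjusted p = 1.3e-09). Between knockdown and PRGL493 the difference did not pass the test (log2 fold change -0.22, SE 0.14, adjusted p = 0.21). Both falls were measured against the same 3 control libraries. For SNAI1 a state of those libraries therefore cannot be told apart from an effect of ACSL4. Histone acetylation itself was not analysed here.

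**Figure D1:**
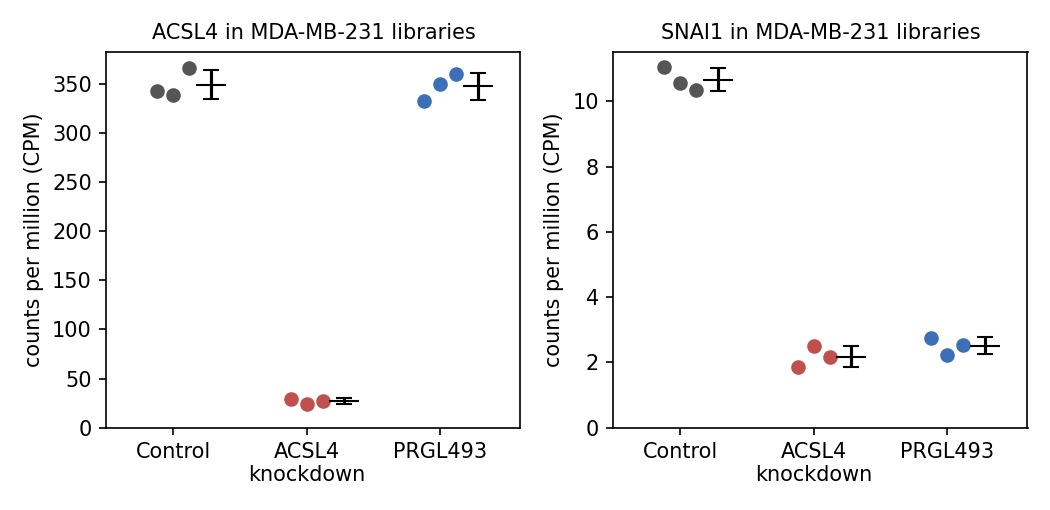
ACSL4 (left) and SNAI1 (right) in CPM (vertical axes, linear) in the 3 control, 3 knockdown and 3 PRGL493 libraries, each point being a library, and the horizontal line and bar give the mean ± SD of the group. ACSL4 was low only in the knockdown libraries (27.0 CPM against 349 and 348 CPM), whereas SNAI1 was at 2.18 CPM in knockdown and 2.51 CPM in PRGL493 libraries against 10.7 CPM in control.

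Knockdown of ACSL4 was compared with the empty vector to ask what the loss of the enzyme changes in these cells. Among genes with a mean log2 CPM of at least 2, the deepest falls included several that growth signals switch on within minutes. FOSB, an AP-1 subunit, dropped to 1.2% of control (201 ± 11.9 to 2.38 ± 0.687 CPM, n = 3 per group, log2 fold change -6.38, SE 0.21, adjusted p = 1.4e-07). HES1, a repressor downstream of Notch, dropped to 1.44% (374 ± 56 to 5.35 ± 1.12 CPM, log2 -6.12, SE 0.16, adjusted p = 2.3e-09). The zinc finger factors EGR3 (27.4 to 0.462 CPM, log2 -5.85, SE 0.18, adjusted p = 2.5e-13) and EGR2 (23.0 to 1.13 CPM, log2 -4.34, SE 0.11, adjusted p = 6.1e-15), and the orphan nuclear receptor NR4A1 (49.8 to 3.56 CPM, log2 -3.81, SE 0.10, adjusted p = 8.0e-15) fell as well. The other genes with the largest falls were ACSL4 itself, the histone gene HIST2H2BE (24.8 to 1.88 CPM, log2 -3.70, SE 0.18, adjusted p = 2.3e-08) and DUSP1. The last, a phosphatase that switches off MAP kinases, had an adjusted p of 2.2e-15 (467 ± 35.0 to 48.2 ± 4.41 CPM, log2 -3.27, SE 0.07). FOSB overlaps ERCC1, and because counting by strand is not stated its level may include reads of that gene.

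The largest rise, with the same limit on level, was in COL1A2, a chain of type I collagen on chromosome 7 (94394561 to 94431232), from 21.8 ± 1.08 to 89.4 ± 1.2 CPM (log2 fold change 2.04, SE 0.06, adjusted p = 8.7e-14). CXCR4, the receptor of the chemokine CXCL12, rose from 5.16 to 16.9 ± 1.24 CPM (1.71, SE 0.12, adjusted p = 8.8e-09). ATP8A1, a flippase of aminophospholipids, rose from 3.99 to 10.8 ± 2.74 CPM (1.44, SE 0.17, adjusted p = 2.0e-05). DDIT4, an inhibitor of mTORC1 signalling, went from 211 ± 10.5 to 487 ± 36.9 CPM (1.21, SE 0.06, adjusted p = 1.5e-10). The zinc finger genes ZNF564 (3.67 to 9.06 CPM, log2 fold change 1.30) and ZNF93 (3.87 to 9.02 CPM, log2 1.22) rose with adjusted p of 1.2e-07 and 9.3e-06. ALPP, the placental alkaline phosphatase (5.54 to 17.5 CPM, log2 1.66), and PRSS2, a trypsinogen (3.38 to 8.16 CPM, log2 1.27), have near-identical paralogs with which reads may be shared, so their levels are uncertain. In all 2083 genes were higher and 2167 lower of 14135 tested, and 97 and 234 of these changed at least 2-fold. The median size of a called change was 0.33 on the log2 scale. Of the calls 49.0% were higher, against 59.8% when libraries were scaled by their totals alone and 58.7% with upper-quartile factors.

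Of 29 immediate early genes tested, 28 fell in knockdown cells (29 with p-values adjusted over the list alone), with a median log2 fold change of -1.29 (camera, adjusted p = 2.6e-30, adjusted p = 0.013 with an estimated correlation). FOS, an AP-1 subunit, went from 318 to 45.2 CPM (log2 fold change -2.82, SE 0.06) and ATF3, a stress-induced factor also held by the integrated stress response list, from 207 to 29.9 CPM (-2.80, SE 0.07). Inflammatory cytokines and NF-kB genes fell in 19 of 27 cases and rose in 3 (20 and 3 adjusted over the list alone, median -0.38, adjusted p = 9.5e-09, adjusted p = 0.047 with an estimated correlation). Among them were NFKBIZ, an inducible NF-kB cofactor (312 to 50.2 CPM, log2 -2.63), the neutrophil chemokine CXCL2 (203 to 61.7 CPM, log2 -1.72), IL6 (255 to 96.0 CPM, log2 -1.41) and IL1B (171 to 76.4 CPM, log2 -1.16). YAP targets fell in 11 of 23 cases and rose in 1 (12 and 1 adjusted over the list alone, median -0.17, adjusted p = 7.9e-05, adjusted p = 0.086 with an estimated correlation). The matricellular proteins CTGF (1895 ± 84.7 to 211 ± 13.8 CPM, log2 -3.17, SE 0.06) and CYR61 (4769 to 1846 CPM, log2 -1.37) were among the members that fell. The p53 targets had 12 of 27 members lower and 1 higher, both over all genes and adjusted over the list alone (median -0.11, adjusted p = 0.00032, adjusted p = 0.047 with an estimated correlation). BTG2, an antiproliferative factor, fell by 2.14 and CDKN1A, the p21 inhibitor of cyclin-dependent kinases, fell by 0.83 on the log2 scale. GADD45A, which is also a member of the YAP list, fell by 1.73. Breast stem-like genes fell in 9 of 16 cases and rose in 2, with the same counts adjusted over the list alone (median -0.23, adjusted p = 0.00024, adjusted p = 0.047 with an estimated correlation). They included HES1, SOX9 (177 to 77.0 CPM, log2 -1.20), MYC (397 to 188 CPM, log2 -1.07) and KLF4 (92.4 to 57.1 CPM, log2 -0.70), of which MYC and KLF4 also belong to the immediate early list.

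Of 35 G1/S genes, 28 rose in knockdown cells (30 adjusted over the list alone, median log2 fold change 0.30, camera, adjusted p = 6.6e-11, adjusted p = 0.047 with an estimated correlation). MCM6 (75.2 to 105 CPM, log2 0.48, SE 0.05) and MCM3 (122 to 158 CPM, log2 0.37), subunits of the replicative helicase, and CDC6, which loads it (55.9 to 77.2 CPM, log2 0.47), were among the members with the smallest adjusted p. Of 46 G2/M genes 30 rose (33 higher and 1 lower adjusted over the list alone, median 0.23, adjusted p = 3.9e-08, adjusted p = 0.047 with an estimated correlation). Among them were HJURP, the chaperone of the centromeric histone (36.4 to 54.5 CPM, log2 0.58), the mitotic kinase AURKB (0.50) and BIRC5, or survivin (0.45). Of 48 matched replication-dependent histones only 8 passed the filter on low counts. Of these 8 members 5 were lower (6 adjusted over the list alone, median -1.03, adjusted p = 0.0021, adjusted p = 0.069 with an estimated correlation). They included HIST1H1C, a linker histone (26.7 to 13.5 CPM, log2 -0.99, SE 0.10), and HIST2H2AA3 (-1.77), which has a near-identical copy and is uncertain.

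Cytosolic ribosomal proteins rose in 52 of 75 cases (60 adjusted over the list alone, median log2 fold change 0.25, camera, adjusted p = 9.5e-13, adjusted p = 0.48 with an estimated correlation). RPS15A (113 to 157 CPM, log2 0.47, SE 0.07), RPL36 (0.43, SE 0.06), RPL34 (0.38, SE 0.05) and RPL23 (0.36, SE 0.05) had the smallest adjusted p. Ribosomal protein genes have processed pseudogenes with which reads may be shared. Without knockdown replicate 2, the library in which short transcripts stood high, 47 members were called and the median was 0.18. Genes of oxidative phosphorylation rose in 14 of 53 cases and fell in 1, with the same counts adjusted over the list alone (median 0.13, adjusted p = 0.0043, adjusted p = 0.77 with an estimated correlation). The list call was lost without knockdown replicate 2 (adjusted p = 0.34) and after a length and GC trend, an alternative chosen after seeing the data, was removed (adjusted p = 0.29). Named members went both ways, with COX7B at 0.37 (SE 0.08) and COX6C, also a subunit of cytochrome c oxidase, at -0.38 (SE 0.07). TGF-beta targets fell in 11 of 24 cases and rose in 4 (12 and 4 adjusted over the list alone, median -0.17, adjusted p = 0.021, adjusted p = 0.14 with an estimated correlation). This call too was lost without knockdown replicate 2 (adjusted p = 0.056) and with the trend removed (adjusted p = 0.16). JUNB (-1.29) and CTGF fell, while the ligand BMP4 rose (0.66, SE 0.05).

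In knockdown cells cholesterol synthesis genes fell in 16 of 26 cases and rose in 1 (17 and 1 adjusted over the list alone, median log2 fold change -0.25, camera, adjusted p = 2.7e-06, adjusted p = 0.16 with an estimated correlation). STARD4, a sterol carrier, fell from 65.4 to 27.3 CPM (-1.26, SE 0.07), INSIG1, which holds the sterol sensor in the endoplasmic reticulum, from 161 ± 3.75 to 90.1 ± 2.04 CPM (-0.83, SE 0.05). LSS, lanosterol synthase, went from 169 to 109 CPM (-0.63, SE 0.06). Fatty acid synthesis genes fell in 9 of 22 cases and rose in 1, with the same counts adjusted over the list alone (median -0.14, adjusted p = 0.0079, adjusted p = 0.074 with an estimated correlation). FASN, the fatty acid synthase (chromosome 17, 82078333 to 82098332), fell from 373 ± 9.0 to 205 ± 24.1 CPM (-0.86, SE 0.08, adjusted p = 1.0e-06), and SCD, the stearoyl-CoA desaturase, from 823 to 518 CPM (-0.67, SE 0.05). NRF2 targets fell in 11 of 28 cases and rose in 2 (13 and 3 adjusted over the list alone, median -0.14, adjusted p = 0.0043, adjusted p = 0.42 with an estimated correlation). They included the haem oxygenase HMOX1 (-0.66) and SRXN1 (-0.60), and with the length and GC trend removed 18 were called lower. Interferon-stimulated genes fell in 16 of 39 cases and rose in 3 (17 and 4 adjusted over the list alone, median -0.15, adjusted p = 0.0021, adjusted p = 0.050 with an estimated correlation), and GBP1 (-0.61) and SAMD9 (-0.58) were among them.

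Several lists tied to the question of the series were not called as groups in knockdown cells, although members changed. Of 8 EMT transcription factors 3 fell, SNAI1, SNAI2 (51.4 ± 3.42 to 27.2 ± 1.14 CPM, log2 fold change -0.92, SE 0.07, adjusted p = 2.6e-08) and FOXC1 (-0.46, SE 0.08), with the same count adjusted over the list alone (camera, adjusted p = 0.14). With the filter of at least 1 CPM in 3 libraries the EMT transcription factors were called (adjusted p = 0.032), and with an estimated correlation and the usual filter they were not (0.28). Mesenchymal genes rose in 7 and fell in 5 of 23 cases (adjusted p = 0.58), with COL1A2 and the cadherin CDH11 (103 to 167 CPM, log2 0.69, SE 0.05) higher. Epithelial genes rose in 7 and fell in 6 of 26 (adjusted p = 0.65), with the adhesion molecule EPCAM (18.1 to 30.4 CPM, log2 0.74, SE 0.07) higher. Proteases and invasion genes rose in 3 and fell in 7 of 27 cases (4 and 7 adjusted over the list alone, adjusted p = 0.49), with the collagenase MMP1 (36.4 to 16.2 CPM, log2 -1.17, SE 0.08) lower. Histone acetyltransferases rose in 2 and fell in 2 of 23 (adjusted p = 0.50). Histone deacetylases rose in 1 and fell in 6 of 22 (adjusted p = 0.36), with SIRT2 (-0.45, SE 0.06) and HDAC5 (-0.37, SE 0.06) lower. Acetyl-CoA supply genes rose in 5 and fell in 6 of 30 (adjusted p = 0.65), with ACLY, which makes acetyl-CoA from citrate, lower (-0.32, SE 0.05). The ACSL family rose in 1 and fell in 4 of 12 (adjusted p = 0.35), with ACSL3 lower (136 to 99.0 CPM, log2 -0.46, SE 0.05) beside ACSL4 and the transporter SLC27A2 higher (0.99, SE 0.12). Of 21 polyunsaturated lipid remodelling genes 1 rose and 4 fell (adjusted p = 0.36), among them PTGS2, the inducible cyclooxygenase (0.842 to 0.190 CPM, log2 -2.12, SE 0.31). Of 28 ferroptosis genes 5 rose and 9 fell (6 and 9 adjusted over the list alone, adjusted p = 0.26), with SAT1 lower (-0.66, SE 0.06), and the list was called with the length and GC trend removed (adjusted p = 0.048, and 0.34 with an estimated correlation as well). Where no other count is given in this paragraph, the counts adjusted over the list alone were the same.

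PRGL493 was compared with the empty-vector control to ask what the inhibitor changes in cells without the hairpin. Rises are given first, for genes with a mean log2 CPM of at least 2. LPIN1, a phosphatidate phosphatase, went from 44.3 ± 1.27 to 117 ± 2.78 CPM (n = 3 per group, log2 fold change 1.40, SE 0.06, adjusted p = 6.7e-12). SCD went from 823 ± 18.9 to 1874 ± 81.0 CPM (1.19, SE 0.05, adjusted p = 1.6e-11) and FADS2, a desaturase of polyunsaturated fatty acids, from 143 to 324 CPM (1.18, SE 0.06, adjusted p = 5.8e-11). VIPR1, a receptor of vasoactive intestinal peptide (17.7 ± 1.54 to 57.5 ± 3.56 CPM, log2 1.70, SE 0.08), and CRTAM, an adhesion molecule of lymphocytes (2.36 to 6.41 CPM, log2 1.44, SE 0.12), also rose. So did CYP1B1, a cytochrome P450 (388 to 963 ± 48.8 CPM, log2 1.31, SE 0.05), and PRKCDBP, a caveolar protein (31.2 to 72.5 CPM, log2 1.22, SE 0.08). FADS2 overlaps FADS1 and CYP1B1 overlaps RMDN2, so their levels are uncertain without counting by strand.

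With the same limit on level, the largest falls with PRGL493 were those of HES1 (374 ± 56.0 to 34.1 ± 0.242 CPM, log2 fold change -3.46, SE 0.13, adjusted p = 3.2e-08), FOSB (201 to 21.4 ± 4.72 CPM, log2 -3.24, SE 0.17, adjusted p = 1.5e-06) and NR4A1 (49.8 to 6.05 CPM, log2 -3.05, SE 0.09, adjusted p = 1.4e-13). TNS4, a focal adhesion protein, fell from 18.3 to 3.38 CPM (-2.45, SE 0.10) and the matrix protein TNC, or tenascin C, from 148 ± 2.11 to 27.2 ± 0.595 CPM (-2.44, SE 0.06, adjusted p = 6.1e-14). EGR3 (-2.41, SE 0.13), the Wnt antagonist SOST (44.6 to 8.54 CPM, log2 -2.38, SE 0.08) and the kinase NUAK2, a YAP target (22.5 to 4.38 CPM, log2 -2.34, SE 0.12), completed this group. TNC overlaps DEC1, which leaves the same doubt about strand. In all 3030 genes were higher and 2879 lower of 14135 tested, 70 and 451 of them by at least 2-fold, and the median size of a called change was 0.36 on the log2 scale. Of the calls 51.3% were higher, against 46.2% with upper-quartile factors and 54.9% with libraries scaled by their totals alone.

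Cholesterol synthesis genes rose with PRGL493 in 24 of 26 cases and fell in 1 (25 and 1 adjusted over the list alone, median log2 fold change 0.62, camera, adjusted p = 2.3e-12, adjusted p = 0.066 with an estimated correlation). DHCR7, the reductase of the last step of the pathway (145 to 267 CPM, log2 0.89, SE 0.05), and INSIG1 (161 to 287 ± 14.4 CPM, log2 0.84, SE 0.05) were among the members with the smallest adjusted p. Fatty acid synthesis genes rose in 14 of 22 cases and fell in 1 (15 and 1 adjusted over the list alone, median 0.31, adjusted p = 0.00021, adjusted p = 0.059 with an estimated correlation). FASN went from 373 to 832 ± 66.6 CPM (1.16, SE 0.08) and SREBF1, the transcription factor of the pathway, from 199 to 310 CPM (0.64, SE 0.06). PPAR targets fell in 12 of 21 cases and rose in 2 (14 and 2 adjusted over the list alone, median -0.36, adjusted p = 0.00056, adjusted p = 0.059 with an estimated correlation). ANGPTL4, an inhibitor of lipoprotein lipase (9.96 to 2.80 CPM, log2 -1.84, SE 0.13), LPL, the lipase itself (-1.32), UCP2, a mitochondrial carrier (-0.91), and PLIN2, a lipid droplet coat protein (-0.56), were lower. Xenobiotic response genes rose in 4 of 8 cases (5 adjusted over the list alone, median 0.42, adjusted p = 0.0028, adjusted p = 0.066 with an estimated correlation). CYP1A1 (11.8 to 26.5 CPM, log2 1.17, SE 0.09) was higher beside CYP1B1. NRF2 targets rose in 11 of 28 cases and fell in 1 (11 and 2 adjusted over the list alone, median 0.12, adjusted p = 0.0061, adjusted p = 0.29 with an estimated correlation), and with the length and GC trend removed NRF2 targets were called higher in 20.

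With PRGL493 integrated stress response genes were lower in 26 of 31 cases and higher in 1, with the same counts adjusted over the list alone (median log2 fold change -0.61, camera, adjusted p = 1.7e-11, adjusted p = 0.066 with an estimated correlation). GDF15, a stress-induced cytokine that is also a p53 target, went from 151 ± 10.2 to 33.4 ± 0.902 CPM (-2.18, SE 0.08). ASNS, asparagine synthetase, fell from 333 to 127 CPM (-1.39, SE 0.05) and PSAT1, of serine synthesis, from 306 to 150 CPM (-1.03, SE 0.05). The unfolded protein response list had 18 of 26 members lower and 2 higher, the same adjusted over the list alone (median -0.31, adjusted p = 1.2e-05, adjusted p = 0.095 with an estimated correlation). Its members HSPA5, the main chaperone of the endoplasmic reticulum (3697 to 1761 CPM, log2 -1.07, SE 0.05), and HSP90B1 (2392 to 1489 CPM, log2 -0.68, SE 0.05) fell. The 27 p53 targets were not called as a group (4 higher and 12 lower, 5 and 12 adjusted over the list alone, adjusted p = 0.062), but were called without PRGL493 replicate 3 (adjusted p = 0.045). With an estimated correlation and all libraries the adjusted p was 0.19.

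Immediate early genes fell with PRGL493 in 22 of 29 cases and rose in 3, with the same counts adjusted over the list alone (median log2 fold change -0.65, camera, adjusted p = 1.9e-10, adjusted p = 0.059 with an estimated correlation). Besides NR4A1 they included the MAP kinase phosphatases DUSP5 (588 to 171 CPM, log2 -1.78, SE 0.05) and DUSP6 (338 to 176 CPM, log2 -0.94, SE 0.04) and ATF3 (207 to 51.3 CPM, log2 -2.02, SE 0.06). Inflammatory cytokines and NF-kB genes fell in 16 of 27 cases and rose in 6, the same adjusted over the list alone (median -0.67, adjusted p = 1.2e-05, adjusted p = 0.075 with an estimated correlation). IL1A fell from 394 ± 15 to 92.4 ± 2.02 CPM (-2.09, SE 0.05), CXCL2 from 203 to 58.2 CPM (-1.81) and IL6 from 255 to 104 CPM (-1.28). YAP targets fell in 13 of 23 cases and rose in 3, the same adjusted over the list alone (median -0.26, adjusted p = 9.3e-05, adjusted p = 0.083 with an estimated correlation). Their members CTGF (1895 to 426 ± 3.01 CPM, log2 -2.15, SE 0.06), IGFBP3 (162 to 52.0 CPM, log2 -1.64) and F3, or tissue factor (1429 to 724 CPM, log2 -0.98), were lower. TGF-beta targets fell in 13 of 24 cases and rose in 4 (13 and 5 adjusted over the list alone, median -0.28, adjusted p = 0.0031, adjusted p = 0.075 with an estimated correlation). The matrix protein THBS1 fell from 3138 to 1683 CPM (-0.90, SE 0.05). Breast stem-like genes fell in 9 of 16 cases and rose in 4, the same adjusted over the list alone (median -0.42, adjusted p = 0.014, adjusted p = 0.087 with an estimated correlation). HES1, PROCR (-1.27) and KLF4 (-1.02) were lower.

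With PRGL493 mesenchymal genes fell in 14 of 23 cases and rose in 2 (15 and 2 adjusted over the list alone, median log2 fold change -0.30, camera, adjusted p = 5.4e-05, adjusted p = 0.090 with an estimated correlation). They included COL1A2 (21.8 to 12.7 CPM, log2 -0.78, SE 0.07) and the fibronectin receptor subunit ITGA5 (-0.72). Epithelial genes also fell, in 11 of 26 cases, and rose in 4, the same adjusted over the list alone (median -0.15, adjusted p = 0.013, adjusted p = 0.20 with an estimated correlation). The tight junction proteins CLDN1 (-1.41, SE 0.07) and CLDN7 (80.8 to 34.4 CPM, log2 -1.23, SE 0.08) and EPCAM (18.1 to 9.94 CPM, log2 -0.86, SE 0.08) were lower. Basal breast genes fell in 8 of 15 cases (8 lower and 1 higher adjusted over the list alone, median -0.67, adjusted p = 0.0035, adjusted p = 0.066 with an estimated correlation). The laminin chain LAMB3 (-0.79) fell. Proteases and invasion genes fell in 14 of 27 cases and rose in 5 (15 and 5 adjusted over the list alone, median -0.14, adjusted p = 0.019, adjusted p = 0.29 with an estimated correlation). MMP1 (36.4 to 15.8 CPM, log2 -1.20), the gelatinase MMP9 (1.29 to 0.313 CPM, log2 -2.03, SE 0.28) and the urokinase PLAU (810 to 536 CPM, log2 -0.60) fell. Of 8 EMT transcription factors 3 fell, SNAI1, SNAI2 (51.4 to 33.2 ± 1.84 CPM, log2 -0.63, SE 0.07) and KLF8, with the same count adjusted over the list alone, and the list was not called (adjusted p = 0.24). The call of KLF8 (-1.07, SE 0.39, adjusted p = 0.037) was lost with no filter (0.055), with DESeq2 (0.089), and without control replicate 1 (0.17) or 3 (0.057) or PRGL493 replicate 1 (0.16) or 2 (0.083). Haematopoietic genes fell in 5 of 7 cases, the same adjusted over the list alone (median -0.47, adjusted p = 0.0037, adjusted p = 0.096 with an estimated correlation), led by LAPTM5 (60.2 to 26.0 CPM, log2 -1.21, SE 0.06). Endothelial genes fell in 3 of 6 cases (same count adjusted over the list alone, median -0.51, adjusted p = 0.024, adjusted p = 0.20 with an estimated correlation), led by ESAM (-1.08, SE 0.08).

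Of 35 G1/S genes 29 rose with PRGL493 (31 adjusted over the list alone, median log2 fold change 0.51, camera, adjusted p = 2.3e-12, adjusted p = 0.059 with an estimated correlation). They included the transcription factor E2F1 (0.65, SE 0.06), MCM4 (0.62, SE 0.05), MCM3 (122 to 185 CPM, log2 0.60, SE 0.05) and MCM7 (0.59, SE 0.05). Of 46 G2/M genes 15 rose and 2 fell (14 and 2 adjusted over the list alone, median 0.09, adjusted p = 0.029, adjusted p = 0.20 with an estimated correlation). GTSE1 (0.55) and BIRC5 (0.49) were higher, and with the length and GC trend removed 24 were called higher. Histone acetyltransferases rose in 9 of 23 cases, the same adjusted over the list alone (median 0.18, adjusted p = 0.016, adjusted p = 0.29 with an estimated correlation). The coactivator NCOA2 stood at 0.53 (SE 0.10) and HAT1, which acetylates new histones, at 0.33 (SE 0.05). Histone deacetylases rose in 5 and fell in 2 of 22 (adjusted p = 0.22). Acetyl-CoA supply genes rose in 11 and fell in 6 of 30 (12 and 6 adjusted over the list alone, adjusted p = 0.45), with ACSS2, which makes acetyl-CoA from acetate, higher (71.7 to 105 CPM, log2 0.55, SE 0.06). The ACSL family rose in 2 and fell in 1 of 12 (adjusted p = 0.60), with ACSL3 higher (136 to 184 CPM, log2 0.44, SE 0.05). Polyunsaturated lipid remodelling genes rose in 7 and fell in 3 of 21 (adjusted p = 0.24), with FADS1 higher (0.65, SE 0.05) and PTGS1 lower (-1.32, SE 0.08). Ferroptosis genes rose in 6 and fell in 7 of 28 (7 and 8 adjusted over the list alone, adjusted p = 0.85). For the deacetylases, the ACSL family and the lipid remodelling genes the counts adjusted over the list alone were the same.

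Cytosolic ribosomal proteins fell with PRGL493 in 21 of 75 cases and rose in 1 (20 lower adjusted over the list alone, median log2 fold change -0.07, camera, adjusted p = 0.013, adjusted p = 0.73 with an estimated correlation). RPL12 stood at -0.44 (SE 0.08), RPS2 at -0.41 (SE 0.07) and RPL3 at -0.40 (SE 0.06). Interferon-stimulated genes fell in 11 of 39 cases and rose in 3, the same adjusted over the list alone (median -0.10, adjusted p = 0.044, adjusted p = 0.12 with an estimated correlation). OASL stood at -1.03 (SE 0.10). The ribosomal call was lost without PRGL493 replicate 2 (adjusted p = 0.13), and with the length and GC trend removed (adjusted p = 0.31). With that trend removed 10 ribosomal members were called higher and 15 lower. The call of interferon-stimulated genes was lost without control replicate 3 (adjusted p = 0.079), PRGL493 replicate 1 (0.058) or 3 (0.060) and with the trend removed (0.092). That of G2/M genes was lost without control replicate 1 (0.055) or PRGL493 replicate 3 (0.063) and with the 1 CPM filter (0.061).

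**Figure D2:**
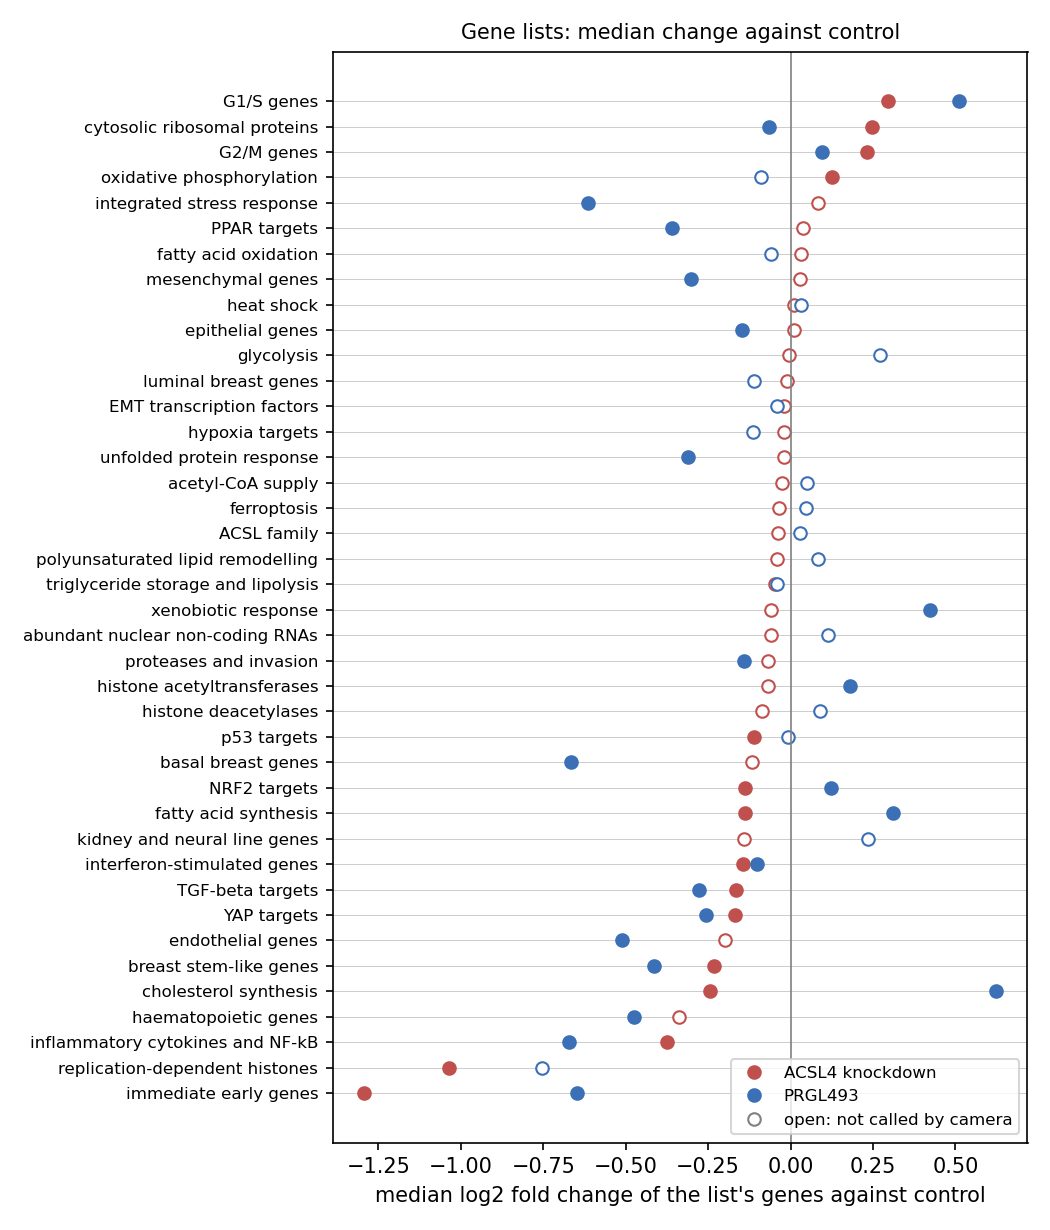
Median log2 fold change against control (horizontal axis) of the genes of each list (vertical axis) in knockdown (red) and PRGL493 (blue); filled points are lists that camera called with the preset correlation, open points are not called, and no error is drawn. Immediate early genes lay at -1.29 and -0.65, G1/S genes at 0.30 and 0.51, and cholesterol synthesis genes at -0.25 in knockdown and 0.62 with PRGL493.

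The changes of both treatments were set side by side to ask how far the inhibitor and the loss of the enzyme move the same genes. Ranked by the smaller of both changes, the largest common falls were those of HES1, FOSB, NR4A1, EGR3 and 2 genes of lower level. These were TREM1, a receptor of myeloid cells (30 to 46 counts per control library, 4 to 8 per knockdown library and 4 to 7 per PRGL493 library), and DUSP2, a MAP kinase phosphatase (8.39 CPM in control, 1.03 in knockdown and 1.2 with PRGL493). The largest common rises were those of CALCR, the calcitonin receptor (0.682 to 2.44 and 2.38 CPM), ATOH8, a transcription factor (0.941 to 3.30 and 2.07 CPM), and ISM1, a secreted inhibitor of angiogenesis (3.33 to 7.60 and 6.98 CPM). The others were the zinc finger genes ZKSCAN4 (3.11 to 6.81 and 6.94 CPM), ZNF443 (1.15 to 2.87 and 2.41 CPM) and ZNF547 (0.628 to 1.67 and 1.31 CPM), whose call with PRGL493 was lost without control replicate 2 (adjusted p = 0.067). The genes that went opposite ways with the largest smaller change were all of low level. They were SERPINB2, a protease inhibitor (1.45 CPM in control, 4.16 in knockdown and 0.450 with PRGL493), SPN, a leukocyte sialoprotein (0.308, 0.726 and 0.0889 CPM), LCN10, a lipocalin (0.534, 1.22 and 0.188 CPM), and PIGR, the receptor of polymeric immunoglobulins (0.497, 1.01 and 0.193 CPM). SERPINB2 overlaps SERPINB10, and ZNF547 overlaps TRAPPC2B, so their levels are uncertain.

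With a limit of mean log2 CPM of at least 2, which was added after the data were seen, CTGF and ATF3 joined the common falls (ATF3 with PRGL493 at -2.02). DDIT4 (211 to 487 and 416 CPM) and CRTAM (2.36 to 4.53 and 6.41 CPM) joined the common rises, as did ZNF250 (7.15 to 13.8 and 14.8 CPM) and ZNF564 (3.67 to 9.06 and 6.90 CPM). With that limit genes that went opposite ways were led by FASN, CLDN11, a tight junction protein (33.1 CPM in control, 63.5 in knockdown and 15.8 with PRGL493), LIPG, endothelial lipase (25.7, 13 and 48.3 CPM), and TRIM29 (15.4, 31.2 and 7.85 CPM).

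In all 722 genes were called higher and 767 lower in both comparisons, and 709 were called in opposite directions. Independent lists of these sizes would share 447 and 441 genes in the same direction and 889 in opposite directions. Simulated unchanged groups against the same controls shared 0.13 genes in the same direction on average and at most 2. With no gene changed hardly any is called, so that count is no expectation for lists of these sizes. Of the 1489 genes called alike, 535 also differed between the treatments, 229 with the larger change in knockdown and 306 with PRGL493. Across the 14135 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.319 and a Spearman rho of 0.20, against simulated means of 0.513 and 0.468 for unchanged groups that share controls. The same sign was seen in 54.5% of genes (67.1% simulated). No gene changed in the simulations, so r, rho and the share of equal signs there come from the shared controls alone. The lower observed values therefore do not show that the treatments were less alike than unchanged groups. The covariance was 0.0626 against a simulated 0.0272, a difference of 0.0354. The 3 control libraries cannot be split into 2 parts of at least 2, so part of the excess overlap may come from the shared controls.

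**Figure D3:**
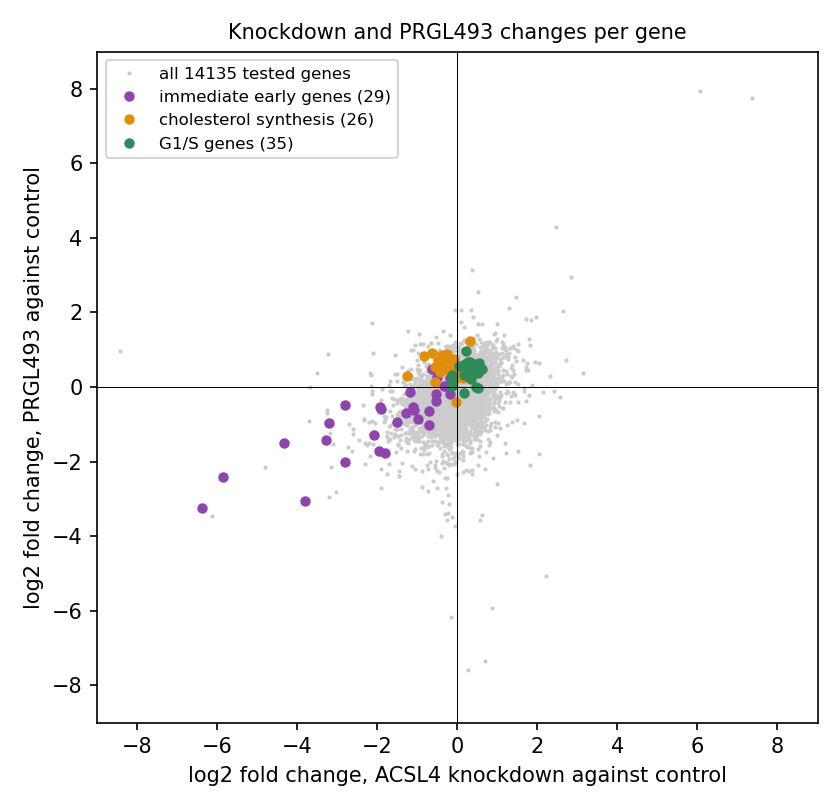
Log2 fold change of each of 14135 genes in knockdown against control (horizontal axis) and in PRGL493 against control (vertical axis); grey points are all genes and coloured points are 29 immediate early, 26 cholesterol synthesis and 35 G1/S genes. The medians in knockdown and PRGL493 were -1.29 and -0.65 for immediate early genes, -0.25 and 0.62 for cholesterol synthesis and 0.30 and 0.51 for G1/S genes, and Pearson r across all genes was 0.319.

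Knockdown and PRGL493 cells were compared directly, which uses no control library. Beside COL1A2 (89.4 ± 1.2 CPM in knockdown and 12.7 ± 0.481 with PRGL493, n = 3 per group, log2 fold change 2.82, SE 0.06, adjusted p = 6.1e-15), the genes that stood highest in knockdown, with the same limit on level, were SERPINA3, an antiprotease (12.1 and 2.08 CPM, log2 2.54, SE 0.11), the cytokine IL24 (75.1 and 14.1 CPM, log2 2.41, SE 0.07) and C17orf107 (10.9 and 2.20 CPM, log2 2.28, SE 0.14), which overlaps CHRNE on the other strand and is uncertain. Those that stood lowest were ACSL4 (-3.69, SE 0.07), EGR3 (-3.45, SE 0.21), FOSB (-3.14, SE 0.22) and EGR2 (-2.84, SE 0.11). Of 14135 genes 3454 were higher and 3676 lower in knockdown, 448 and 189 of them by at least 2-fold. Of the calls 48.4% were higher, against 58.4% with upper-quartile factors and 51.9% with libraries scaled by their totals alone. The median size of a called difference was 0.38 on the log2 scale.

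Cholesterol synthesis genes were lower in knockdown than with PRGL493 in 24 of 26 cases and higher in 1, the same adjusted over the list alone (median log2 fold change -0.88, camera, adjusted p = 1.8e-13, adjusted p = 0.088 with an estimated correlation). INSIG1 stood at -1.67 (SE 0.05), STARD4 at -1.56 (SE 0.07) and LSS at -1.53 (SE 0.06). Fatty acid synthesis genes were lower in 16 of 22 cases and higher in 1 (16 and 2 adjusted over the list alone, median -0.39, adjusted p = 4.1e-05, adjusted p = 0.082 with an estimated correlation). FASN was at 24.7% and SCD at 27.7% of their level with PRGL493. NRF2 targets were lower in 17 of 28 cases and higher in 1 (18 and 1 adjusted over the list alone, median -0.38, adjusted p = 2.1e-05, adjusted p = 0.25 with an estimated correlation). Immediate early genes were lower in 23 of 29 cases and higher in 1 (24 and 1 adjusted over the list alone, median -0.61, adjusted p = 2.7e-10, adjusted p = 0.082 with an estimated correlation). FOS stood at -2.34 (SE 0.06) and DUSP1 at -1.85 (SE 0.07). G1/S genes were lower in 18 of 35 cases and higher in 3 (19 and 3 adjusted over the list alone, median -0.18, adjusted p = 0.0076, adjusted p = 0.29 with an estimated correlation). Glycolysis genes were lower in 15 of 23 cases and higher in 5 (16 and 5 adjusted over the list alone, median -0.25, adjusted p = 0.019, adjusted p = 0.58 with an estimated correlation). The lactate carrier SLC16A1 was higher (11.8 and 2.73 CPM, log2 2.11, SE 0.12). Histone acetyltransferases were lower in 14 of 23 cases and higher in 1 (15 and 1 adjusted over the list alone, median -0.31, adjusted p = 0.014, adjusted p = 0.33 with an estimated correlation). Xenobiotic response genes were lower in 5 of 8 cases and higher in 1, the same adjusted over the list alone (median -0.53, adjusted p = 0.034, adjusted p = 0.21 with an estimated correlation).

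Integrated stress response genes were higher in knockdown than with PRGL493 in 24 of 31 cases and lower in 3, the same adjusted over the list alone (median log2 fold change 0.62, camera, adjusted p = 1.3e-08, adjusted p = 0.15 with an estimated correlation). GDF15 stood at 1.83 (SE 0.07) and ASNS at 1.68 (SE 0.05). Unfolded protein response genes were higher in 17 of 26 cases and lower in 1, the same adjusted over the list alone (median 0.33, adjusted p = 2.1e-05, adjusted p = 0.21 with an estimated correlation). PPAR targets were higher in 13 of 21 cases and lower in 3, the same adjusted over the list alone (median 0.55, adjusted p = 0.00064, adjusted p = 0.082 with an estimated correlation), and ANGPTL4 stood at 1.77 (SE 0.13). Mesenchymal genes were higher in 17 of 23 cases and lower in 2 (17 and 3 adjusted over the list alone, median 0.36, adjusted p = 6.1e-05, adjusted p = 0.21 with an estimated correlation). Epithelial genes were also higher, in 14 of 26 cases, and lower in 7 (15 and 7 adjusted over the list alone, median 0.19, adjusted p = 0.034, adjusted p = 0.33 with an estimated correlation). CLDN7 stood at 1.64 (SE 0.08) and EPCAM at 1.60 (SE 0.08).

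Cytosolic ribosomal proteins were higher in knockdown than with PRGL493 in 66 of 75 cases, the same adjusted over the list alone (median log2 fold change 0.35, camera, adjusted p = 2.3e-12, adjusted p = 0.41 with an estimated correlation). With the length and GC trend removed the median was 0.18 and 50 were called higher. RPL9 stood at 0.62 (SE 0.06) and RPL36 at 0.60 (SE 0.06). Oxidative phosphorylation genes were higher in 32 of 53 cases and lower in 3, the same adjusted over the list alone (median 0.21, adjusted p = 0.00036, adjusted p = 0.58 with an estimated correlation). G2/M genes were higher in 25 of 46 cases and lower in 5 (26 and 6 adjusted over the list alone, median 0.18, adjusted p = 0.020, adjusted p = 0.25 with an estimated correlation). As in the comparison with control, short transcripts stood high in knockdown replicate 2. With the length and GC trend removed the calls of oxidative phosphorylation (adjusted p = 0.21), G2/M genes (0.16) and histone acetyltransferases (0.050) were lost. Of the oxidative phosphorylation genes 18 were then called higher and 8 lower. The call of epithelial genes was lost without PRGL493 replicate 3 (0.058) and with the 1 CPM filter (0.063), and that filter also ended the call of xenobiotic response genes (0.056).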

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

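The tests of a state of the control libraries were chosen only after the result was seen, and the removal of a length and GC trend, alone or with an estimated correlation, is an alternative chosen after seeing the data.

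Each result listed first was called in opposite directions in knockdown and with PRGL493 against control, and the direct difference between the treatments was called too. For cholesterol synthesis genes the median log2 fold change between knockdown and PRGL493 was -0.88 (-0.25 in knockdown, 0.62 with PRGL493, camera adjusted p = 1.8e-13). It was 0.35 for cytosolic ribosomal proteins (0.25 and -0.07, adjusted p = 2.3e-12), -0.39 for fatty acid synthesis genes (-0.14 and 0.31, adjusted p = 4.1e-05) and -0.38 for NRF2 targets (-0.14 and 0.12, adjusted p = 2.1e-05). With an estimated correlation none of these 4 lists was called in any comparison. In the same order the adjusted p were 0.16, 0.48, 0.074 and 0.42 in knockdown, 0.066, 0.73, 0.059 and 0.29 with PRGL493, and 0.088, 0.41, 0.082 and 0.25 for the difference. The difference for cytosolic ribosomal proteins had a median of 0.18 with the trend removed. With the trend removed and an estimated correlation, the list test called the difference for cholesterol synthesis (0.042), fatty acid synthesis (0.037) and NRF2 targets (0.042) but not for cytosolic ribosomal proteins (0.37), and of the comparisons with control only fatty acid synthesis with PRGL493 (0.029). The call of cytosolic ribosomal proteins with PRGL493 was lost without PRGL493 replicate 2 (adjusted p = 0.13) and with the trend removed (median -0.02, adjusted p = 0.31). Among genes, SERPINB2 differed by 3.24 (1.52 and -1.73, edgeR adjusted p = 1.8e-08), SPN by 2.98 (1.22 and -1.76, adjusted p = 1.3e-05), LCN10 by 2.68 (1.19 and -1.49, adjusted p = 1.1e-05) and PIGR by 2.28 (1.00 and -1.28, adjusted p = 0.00020). The calls of PIGR against control were weak, with adjusted p of 0.041 and 0.034. In knockdown its call was lost with DESeq2 (0.088) and without any of the 3 control libraries (0.18, 0.061 and 0.075), knockdown replicate 2 (0.14) or 3 (0.088) or PRGL493 replicate 2 (0.051) or 3 (0.050). With PRGL493 the call of PIGR was lost without control replicate 2 (0.12) or 3 (0.11) or PRGL493 replicate 2 (0.10) or 3 (0.12), and DESeq2 ended that of SPN in knockdown (0.053). With a limit on level added after the data were seen, CLDN11 differed by 2.01 (0.94 and -1.07, edgeR adjusted p = 1.8e-12), FASN by -2.02 (-0.86 and 1.16, adjusted p = 5.3e-11), LIPG by -1.89 (-0.98 and 0.91, adjusted p = 6.4e-12) and TRIM29 by 1.99 (1.02 and -0.97, adjusted p = 6.7e-12).

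Cholesterol synthesis genes were lower than control in knockdown and higher with PRGL493. A state of the control libraries would move both comparisons alike, so it gives no difference between the treatments. The direct comparison, which holds no control library, had a median of -0.88, a value that largely restates the changes against control. How this gap divides into a fall in knockdown and a rise with PRGL493 rests on the shared control libraries. A state of those libraries cannot be told apart there. With the length and GC trend removed the knockdown median was -0.26, and without any 1 library the number of members called was at least 81.2% of that with all, which argues against the trend and a single library as the whole cause. The biological difference named by the design, a hairpin in one group and an inhibitor in the other, stays open and untested, as do culture conditions and exposure, which follow the groups.

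Immediate early genes fell in both treatments, with a median of -1.29 in knockdown and -0.65 with PRGL493, and with an estimated correlation the call held in knockdown (adjusted p = 0.013) but not with PRGL493 (0.059) or for the difference (0.082). If high expression in the 3 control libraries were the whole cause, knockdown and PRGL493 would not differ, but their direct comparison had a median of -0.61. That value largely restates the changes against control. With the trend removed the median nearer 0 was -0.63, and without any 1 library the number of members called was at least 90.9% of that with all, which argues against the trend and a single library as the whole cause. For the part common to both treatments (median -0.65 with PRGL493) a state of the control libraries, such as the handling of cells at harvest, cannot be told apart from an effect of ACSL4, because the same 3 libraries serve both comparisons. The further fall in knockdown cannot be assigned to ACSL4 either. Culture conditions, handling and exposure follow the groups, and their part was not tested.

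Cytosolic ribosomal proteins rose in knockdown with a median of 0.25, in a group whose replicate 2 had short transcripts high. With the trend removed the median was 0.17, and without knockdown replicate 2 the number of members called was 90.4% of that with all libraries. The share without replicate 2 argues against that library as the whole cause, although part of the size of the rise may come from it. The trend was fitted to the longest annotated transcript of each gene. Where the expressed transcript is shorter its removal may fall short, so the trend stays open as a cause. The list was not called with an estimated correlation (adjusted p = 0.48), and reads shared with pseudogenes were not tested.

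Each comparison of 3 against 3 libraries allows 10 splits, which are too few for a share under 0.05. Every split but the real one mixes both groups on both sides, so real differences widen its spread. Its counts are therefore low by construction and give no expectation for unchanged groups. In knockdown against control 1 of the 10 splits gave as many called genes as the real split, which was the real one itself (4250 genes), and the highest of the others gave 0. In PRGL493 against control it was likewise 1 of 10 (5909 genes, highest other 0), and in knockdown against PRGL493 1 of 10 (7130 genes, highest other 0). These counts are of edgeR's test. At an unadjusted p below 0.05 the other splits listed up to 933, 324 and 586 genes, against 5767, 7043 and 7958 in the real ones.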

How the results depend on the processing

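The removal of a length and GC trend, alone or with an estimated correlation, was chosen only after the data were seen, and the other alternatives were planned. Among the genes taken by the naming rule and the lists, none that was called changed direction where direction was computed anew. The 2 stricter thresholds were not checked for this, and fry and the estimated correlation kept the main direction. Some lists that were not called had medians near 0 that changed sign with the scaling. ACSL4 and SNAI1 kept their side of the threshold in all 3 comparisons under every scaling, filter, tool, fit and omitted library. Without each library in turn, the log2 fold change of ACSL4 in knockdown ran from -3.76 to -3.61, and that of SNAI1 from -2.41 to -2.19 in knockdown and from -2.16 to -2.02 with PRGL493. At an adjusted p below 0.01 the counts in knockdown fell to 1128 higher and 1340 lower genes, and 809 genes were called in both comparisons in the same direction. Tested against a 1.2-fold change (glmTreat), knockdown gave 377 higher and 583 lower, PRGL493 775 higher and 1187 lower, the direct comparison 2895, and both comparisons alike 337. These tests are stricter by construction. Of 15, 23 and 16 lists called by camera, 6, 0 and 0 were called with an estimated correlation, which allows for genes that vary together. At an unadjusted p below 0.05 that test listed 12, 16 and 8, and fry, which does not compare a list with other genes, called 27, 31 and 33. With the estimated correlation and the trend removed together 5, 5 and 7 lists were called. Other scalings, filters, tools and fits moved no count of genes by over 1.5 times. DESeq2 gave 1907 higher and 2128 lower in knockdown and 2791 and 2798 with PRGL493, and the trend removal gave 2837 and 2512, and 3735 and 3267.

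Leaving out each library in turn, knockdown gave 1418 (without control replicate 3) to 2369 higher genes and 1634 to 2401 lower ones, PRGL493 2333 to 3720 higher and 2375 to 3412 lower, and the direct comparison 5941 to 7303. Genes called alike in both comparisons ran from 1051 to 1797 and Pearson r from 0.265 to 0.449, while r was 0.432 with no filter on low counts and 0.404 with DESeq2. Lists called ran from 14 to 15, 22 to 25 and 15 to 17. Of the results for single genes other than ACSL4 and SNAI1, 55 of these fits lost a call and 2 gained one, against 4569 with no change. Among the list results 9 lost and 9 gained a call, and the cause was not tested. DESeq2 ended 6 gene calls, the trend removal 4, upper-quartile factors 3 and library size alone 2. The 1 CPM filter ended 3 list calls and brought 2 (EMT transcription factors in knockdown, adjusted p = 0.032, and replication-dependent histones in knockdown against PRGL493, 0.020, with 0.28 and 0.25 at an estimated correlation). The trend removal ended 7 and brought 2 (ferroptosis in knockdown, 0.048, and the same histone call, 0.037, with 0.34 and 0.23 when an estimated correlation was used too).

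Replicate numbers are not stated to pair libraries across groups. With the replicate number as a block the calls went from 4250 to 3879 in knockdown, from 5909 to 5635 with PRGL493 and from 7130 to 6857 in the direct comparison. Correlations of same-numbered libraries' deviations from their group means were positive for the control and knockdown pairs (0.108, 0.152 and 0.0619) and negative for each pair with a PRGL493 library (-0.084 to -0.0151). The 6 of 9 libraries that correlated best with their own number give a hint for control and knockdown, from the data and not from the design. The block ended the call of CSF1R, a haematopoietic gene, in knockdown (log2 fold change -0.36, adjusted p = 0.056, against 0.039 without the block and 0.029 to 0.13 over all alternatives). It brought that of replication-dependent histones in knockdown against PRGL493 (camera adjusted p = 0.030, but 0.25 with an estimated correlation and no block). No other call of a named gene or list changed with the block.

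Depth limits how well changes of rare genes are measured. ESRP1, which regulates splicing in epithelial cells, held 0 to 3 counts per PRGL493 library against 21 to 30 per control library, and its SE was 0.48 on the log2 scale.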

Other observations

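The zinc finger genes of the ZNF series, many of which encode repressors of retrotransposons, were chosen after their values were seen. In knockdown 173 of 424 were higher and 21 lower (median log2 fold change 0.21). With PRGL493 198 were higher and 16 lower (median 0.28). The 213 members on chromosome 19 had medians of 0.31 and 0.33, and the 211 elsewhere 0.12 and 0.21. Between knockdown and PRGL493 55 were higher and 89 lower (median -0.03). Because the genes were chosen for these values, no test of the group is given. With the length and GC trend removed, an alternative chosen after seeing the data, the medians were 0.23 and 0.28.

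Of 34 fatty acid oxidation genes 5 rose and 6 fell in knockdown (camera adjusted p = 0.83), and 7 rose and 9 fell with PRGL493 (adjusted p = 0.35), with the same counts adjusted over the list alone. With PRGL493 the carnitine transferase CPT1A went from 53.2 ± 1.71 to 38.3 ± 0.835 CPM (log2 fold change -0.48, SE 0.06), and ACADM, an acyl-CoA dehydrogenase, from 44.2 to 30.6 CPM (-0.53, SE 0.06). Glycolysis genes rose in 15 and fell in 6 of 23 cases with PRGL493 (16 and 7 adjusted over the list alone, adjusted p = 0.055, and called without control replicate 1, 0.046, knockdown replicate 1, 0.035, or knockdown replicate 2, 0.024, but 0.65 with an estimated correlation), with PFKL, a phosphofructokinase, higher (210 to 332 CPM, 0.66, SE 0.06) and the lactate carrier SLC16A1 lower (9.18 to 2.73 CPM, -1.75, SE 0.12). In knockdown 3 of them rose and 7 fell, with the same counts adjusted over the list alone (adjusted p = 0.35, 0.039 without knockdown replicate 2, and 0.82 with an estimated correlation). Hypoxia targets rose in 5 and fell in 12 of 25 cases with PRGL493 (6 and 13 adjusted over the list alone, adjusted p = 0.084), with NDRG1 going from 1931 to 1125 CPM (-0.78, SE 0.05), and in knockdown 5 rose and 5 fell (adjusted p = 0.95). Heat shock genes rose in 5 and fell in 5 of 19 with PRGL493 (adjusted p = 0.82), among them HSPA9, a mitochondrial chaperone (742 ± 12.4 to 330 ± 4.44 CPM, -1.17, SE 0.04). In knockdown 1 rose and 4 fell (adjusted p = 0.67), with the cochaperone BAG3 lower (86.9 to 51.4 CPM, -0.76, SE 0.05). Integrated stress response genes rose in 14 and fell in 9 of 31 in knockdown (15 and 9 adjusted over the list alone, adjusted p = 0.36), with DDIT4 and ATF3 on opposite sides.

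Among the genes of triglyceride storage and lipolysis 5 of 24 rose and 5 fell with PRGL493 (camera adjusted p = 0.85) and 3 rose and 7 fell in knockdown (adjusted p = 0.67), and G0S2, an inhibitor of the lipase PNPLA2, went from 231 to 119 CPM (log2 fold change -0.95, SE 0.06). The nuclear RNA SNHG1 was at 30.5 CPM in control, 59.3 in knockdown and 19.8 with PRGL493. MALAT1 was at 307 CPM in knockdown replicate 2 and at 1175 and 851 CPM in the other knockdown libraries, at 923, 537 and 627 CPM in control and at 484, 805 and 691 CPM with PRGL493. The 9 abundant nuclear non-coding RNAs tested had 1 higher and 1 lower in knockdown (adjusted p = 0.81) and 1 higher and 2 lower with PRGL493 (adjusted p = 0.79).

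Other lists that camera did not call are given as numbers of members higher and lower, with the adjusted p of the list. In knockdown these were unfolded protein response 3 and 2 of 26 (0.83), PPAR targets 4 and 0 of 21 (0.35), xenobiotic response 3 and 0 of 8 (0.45), luminal breast genes 3 and 4 of 13 (0.83) and basal breast genes 1 and 6 of 15 (0.095). Haematopoietic genes had 2 and 2 of 7 (2 and 3 adjusted over the list alone, 0.43), endothelial genes 0 and 3 of 6 (0.18), and kidney and neural line genes 0 and 1 of 4 (0.47). With PRGL493 luminal breast genes had 2 and 6 (0.12), oxidative phosphorylation 5 and 13 of 53 (0.093, but 0.041 without knockdown replicate 2 and 0.042 without PRGL493 replicate 1, and 0.75 with an estimated correlation), replication-dependent histones 1 and 4 of 8 (0.19), and kidney and neural line genes 3 and 0 (3 and 1 adjusted over the list alone, 0.35). Where no other count is given here or above, the counts adjusted over the list alone were the same.

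Between knockdown and PRGL493 the lists not called by camera are given in the same way. Among lipid and acetyl-CoA lists these were ACSL family 3 and 6 of 12 (0.33), polyunsaturated lipid remodelling 4 and 8 of 21 (0.15), ferroptosis 7 and 8 of 28 (0.65), fatty acid oxidation 13 and 8 of 34 (0.33), triglyceride storage and lipolysis 7 and 10 of 24 (0.71), acetyl-CoA supply 9 and 9 of 30 (0.57) and histone deacetylases 3 and 10 of 22 (4 and 10 adjusted over the list alone, 0.13). Signalling and stress lists had TGF-beta targets 9 and 11 of 24 (10 and 11 alone, 0.76), YAP targets 8 and 10 of 23 (0.79), inflammatory genes 8 and 8 of 27 (8 and 9 alone, 0.89), interferon-stimulated genes 9 and 12 of 39 (9 and 13 alone, 0.71), p53 targets 3 and 12 of 27 (0.20), hypoxia targets 13 and 6 of 25 (0.13) and heat shock 5 and 6 of 19 (0.68). Identity lists had EMT transcription factors 1 and 2 of 8 (0.58), breast stem-like genes 4 and 7 of 16 (5 and 7 alone, 0.47), basal breast genes 8 and 4 of 15 (0.096), luminal breast genes 7 and 3 of 13 (0.29), and proteases and invasion 9 and 6 of 27 (10 and 6 alone, 0.20). Haematopoietic genes had 4 and 1 of 7 (0.13), endothelial genes 2 and 2 of 6 (0.57), kidney and neural line genes 1 and 3 of 4 (0.28), abundant nuclear non-coding RNAs 1 and 1 of 9 (0.64) and replication-dependent histones 0 and 5 of 8 (0.067). The histone list was called without knockdown replicate 2 (0.019) and without PRGL493 replicate 1 (0.032), with the 1 CPM filter (0.020) and with the trend removed (0.037), but not with an estimated correlation (0.25, and 0.23 with the trend removed as well). With all libraries and the main settings its median log2 fold change was -0.59 but its mean 0.05, so its direction depended on the summary used.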
